A study of Apis mellifera with 18 samples.

How the data were processed

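RNA was measured by sequencing in 18 libraries of honey bee (Apis mellifera) tissue, 9 from tissue that the labels call tentacles and 9 from mouthparts. Each tissue came from 3 groups, a control group without pollen, a group that collected pear pollen and a group that collected olive (Olea europaea) pollen, called olea here, with 3 libraries in each group. The labels say that total RNA was isolated with a Qiagen kit and that 1.3 ug went into a SMARTER library kit. They do not say whether the replicates were separate animals, pools or repeated preparations, so the p-values measure the spread between these libraries only. The 3 mouthparts libraries coded YH carry conflicting labels. Their title and source name pear pollen and their genotype entry names olea pollen. They were grouped as olea, because the tentacles libraries coded Y are olea and the mouthparts libraries coded LH already form a pear group of 3. The grouping, the comparisons and the rule for naming genes were fixed before the data were examined, and so were the gene lists apart from the domain names described below.

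The authors deposited raw read counts per gene for each library, after mapping with HISAT2. The version of HISAT2, the genome build, the annotation and the counting program are not given in the sources used here. The authors also deposited FPKM values (fragments per kilobase of transcript and per 1e6 fragments) for the same genes and libraries. Other deposited values are the authors' edgeR p-values and log2 fold changes for 8 pairs of groups, which were compared with the values computed here. The table held 17545 genes, 15314 with GB identifiers and 2231 new genes, after 70 overlong lines had been joined to the line before. Library totals ran from 25.9 to 41.4 M (1e6 counts). All intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

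Gene names came from the best KEGG hit that the table itself gives, or else from its protein domain (Pfam) column. A KEGG hit was used where its e-value was at most 1e-10, and 360 weaker hits were ignored. Of 9273 genes with a KEGG hit, 6502 hit a honey bee gene, and 6468 of these hits were found in the reference gene table. As 1572 genes shared a honey bee hit with another gene, a name can stand for a relative of the gene. The genes named yellow-f or yellow-f2-like here carry the Pfam domain of the major royal jelly protein family and are called members of that family.

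Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group, a robust quasi-likelihood fit and the quasi-likelihood F test. The 9 libraries of a tissue shared a fit for the comparisons of pollen groups, which tested 12950 genes in the tentacles and 12285 in the mouthparts. A fit of all 18 libraries tested 13361 genes for the difference between tissues, with the 3 pollen groups weighing equally, and for the interaction of tissue with each pollen. Adjusted p is Benjamini-Hochberg adjusted over the genes of a comparison, and a gene passed at adjusted p under 0.05. Errors of log2 fold changes are standard errors derived from the F statistic, and levels are counts per 1e6 counts (CPM) as mean ± SD over the libraries of a group. Where a group had no count, the fold is a lower bound against a floor of 3 counts over the group. Where it had 1 to 3 counts, the ratio has an exact 95% interval. On simulated data with 200 changed genes, all of at least 5 CPM, the fit recovered 83.6% of genes with a true fold of 1.5 in the tentacles and 82.1% in the mouthparts. It recovered 100% at a fold of 2 in both, and false calls were 4.06% and 6% of the calls. For the interaction with pear, recovery was 68.7% at a fold of 1.5 and 89.6% at 2, with 3.95% false calls.

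There were 25 gene lists: odorant receptors, gustatory receptors, ionotropic chemosensory receptors, odorant binding proteins, chemosensory proteins, biogenic amine signalling, neuropeptides and their receptors, foraging and division of labour genes, circadian clock, heat shock proteins, immune effectors and pathway, detoxification enzymes, cuticle and chitin, digestive proteases and lipases, fatty acid and hydrocarbon synthesis, carbohydrate use, oxidative phosphorylation (nuclear), cytosolic ribosomal proteins, royal jelly and hypopharyngeal gland, venom gland, fat body, muscle, eye photoreceptors, neurons and synapses, and mitochondrially encoded genes. Members were found by words of the gene name or by symbol. For 12 lists, domain names were added after the annotation columns had been seen and before any value was tested. The mitochondrial list had 0 members in the table and gave no result. Lists and KEGG pathways of 10 to 300 tested genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists or pathways of a comparison. Camera with an estimated correlation and fry were run beside it. The members named from a list are those with the smallest p of each list of biology. In addition the 5 largest rises and the 5 largest falls were named, among annotated genes with at least 10 CPM in the higher group and no overlap between the libraries of both groups, which chance gives for 10% of genes in 3 against 3 libraries. In the comparison of tissues the most abundant member of each list was named, and the 5 largest differences in each direction were taken by the same rule.

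Alternatives fixed beforehand were RLE size factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, limma-trend on log2(FPKM + 1), a log2 fold change of at least 1, each library left out in turn, all 18 libraries or only the 6 compared in the fit, the controls only for the tissue difference, and the YH libraries counted as pear. Chosen after seeing the data were the counts without the royal jelly list, with a trend on transcript length taken out (loess, span 0.5, genes of at least 5 CPM), thinned to the smallest library, with LH and YH together as pear, the tissue difference without the conflicting libraries or without the controls, a replicate block within each pollen group, the fits without replicate 2 of the mouthparts pear and olea groups, the estimated correlation for pathways, and list medians under each scaling. The labels give replicates a number and no pairing, and none was used. No library was a copy of another. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Small RNA, which the series title names, was not analysed here.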

Results

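Transcripts were counted in 18 libraries of honey bee tissue, from the tentacles and the mouthparts of bees of 3 groups, a control group without pollen, bees that collected pear pollen and bees that collected olea pollen. Each combination of tissue and group had 3 libraries. Total counts per library, in M (1e6 counts), ran from 26.4 to 41.4 M in the tentacles and from 25.9 to 40.3 M in the mouthparts. The mouthparts libraries of the pear group had 37.0 to 40.3 M, and those of the olea group had 25.9 to 26.8 M. The series title presents the work as a study of collection preference in Italian honey bees. The labels of the 3 mouthparts libraries grouped as olea conflict, as their titles name pear pollen and their genotype entries name olea pollen, and every mouthparts result for olea pollen rests on reading them as olea.

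Libraries of a group lay close together and tissue was the main axis of difference. The first principal component of log2 CPM held 76.8% of the variance and separated all 9 mouthparts libraries from all 9 tentacles libraries. The second held 7.26% and separated the controls from the pollen groups in both tissues. In the mouthparts the pear and olea libraries were apart on it, whereas in the tentacles they overlapped.

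**Figure D1:**
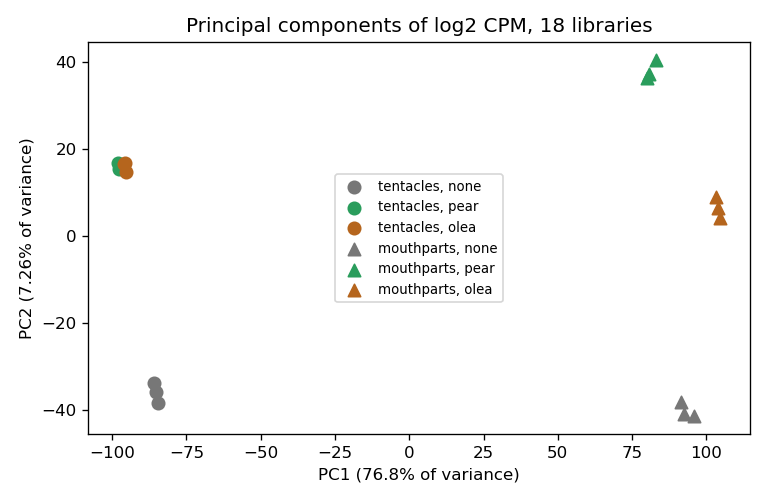
Each point is a library, placed by its scores on the first (x axis) and second (y axis) principal component of log2 CPM, with circles for tentacles, triangles for mouthparts and colours for the pollen groups. The components hold 76.8% and 7.26% of the variance, and the controls lie lowest on the second in both tissues.

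The mouthparts and the tentacles were compared across all pollen groups, with 9 libraries of each. Odorant receptor genes, which detect smells in insect antennae, were higher in the tentacles for 142 of 143 tested members. Odorant receptor 2 (GB40730), in the honey bee the name of the receptors' shared co-receptor, was at 515 ± 73 CPM in the tentacles and at 1.55 ± 2.3 CPM in the mouthparts (n = 9 each). An odorant binding protein (GB55593) was at 21057 ± 1455 CPM in the tentacles and at 76.9 ± 89 CPM in the mouthparts. Proboscipedia (GB51302), a homeotic gene of insect mouthparts, was higher in the mouthparts, at 86.8 ± 14 CPM against 0.137 ± 0.13 CPM. The homeobox gene H55 (GB51295) was at 32.1 ± 3.9 against 0.0714 ± 0.075 CPM, and like proboscipedia it had no count in the tentacles with olea, so no fitted fold is given. SIX3 (GB49751) differed by 6.97 ± 0.20 in log2.

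The odorant receptor list was lower in the mouthparts by camera (adjusted p = 1.4e-24) and kept that call at adjusted p = 9.4e-05 with an estimated correlation. All 142 members were lower also when adjusted over the list alone. All 4 ionotropic receptors were lower in the mouthparts, and ionotropic receptor 25a (GB47387), a co-receptor, differed by -1.74 ± 0.05. The gustatory receptors went both ways, with 4 of 12 higher, 7 lower and 1 not passed. The member not passed was the sugar receptor 43a (GB40382), at 38.4 ± 3.1 CPM in the mouthparts and 39.0 ± 3.3 CPM in the tentacles. Muscle genes were higher in the mouthparts for 28 of 31 members, with titin (GB47977) at 4187 ± 1098 CPM against 1293 ± 155 CPM (camera adjusted p = 6.6e-10, and adjusted p = 0.33 with an estimated correlation). Genes of neurons and synapses were lower in the mouthparts for 33 of 44 members and higher for 8 (adjusted p = 0.00014, and adjusted p = 0.20 with an estimated correlation). A cuticular protein (GB46297) stood at 14034 ± 756 CPM in the mouthparts against 359 ± 51 CPM. Esterase FE4 (GB55921), of a family that breaks down esters, stood at 27724 ± 1525 CPM in the tentacles against 1345 ± 134 CPM and was the most abundant transcript of each tentacles library. Of 50 cuticle and chitin genes, 25 were higher in the mouthparts, 18 lower and 7 not passed. Of 27 venom gland genes, 19 were higher, 6 lower and 2 not passed (adjusted p = 0.0023, and adjusted p = 0.20 with an estimated correlation), and 9 of the 31 genes on that list also belong to other lists.

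In all, 11027 of 13361 genes differed between the tissues by edgeR with Benjamini-Hochberg adjustment, 5238 higher and 5789 lower in the mouthparts. On log2(FPKM + 1), where the median of all genes moved by -0.267 in log2, 31.8% of the calls were higher against 47.5% here. The sugar receptor 43a passed on that scale, at -0.28.

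Tentacles of bees with pear pollen were compared with control tentacles, which asks what differs in this tissue once pollen is collected. Several members of the major royal jelly protein family, the main secreted proteins of the hypopharyngeal gland, fell to near 0. GB55205 fell from 11356 ± 3161 CPM to 1.31 ± 0.31 CPM and GB55204 from 3668 ± 632 CPM to 0.409 ± 0.13 CPM (n = 3 each). Apidaecin (GB47546), an antimicrobial peptide, rose by 2.81 ± 0.20 in log2, from 4.03 ± 1.4 to 28.4 ± 3.2 CPM. The cation channel gene TRPV5 (GB44065) rose by 1.95 ± 0.10, and the armadillo repeat gene gudu (GB49219) by 1.85 ± 0.08. The nuclear receptor HR38 (GB49295), a gene switched on by nerve cell activity in insects, rose from 8.14 ± 1.2 to 19.4 ± 0.50 CPM. The chaperone Hsc3 (GB49117), which folds proteins in the endoplasmic reticulum, fell from 1585 ± 106 to 650 ± 14 CPM.

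Of the royal jelly and hypopharyngeal gland list, 18 of 26 members fell, 2 rose and 6 did not pass, with the same 18 and 2 when adjusted over the list alone. The list held its call with an estimated correlation (adjusted p = 0.025). It took 2.59 ± 0.521% of all counts in control tentacles and 0.127 ± 0.00112% with pear pollen. Of 26 heat shock proteins, 17 fell and 0 rose (18 when adjusted over the list alone), and this call also held with an estimated correlation (adjusted p = 0.025). KEGG genes of protein processing in the endoplasmic reticulum fell for 50 of 143 and rose for 9 (camera adjusted p = 0.0013, and adjusted p = 0.57 with an estimated correlation). Aminoacyl-tRNA biosynthesis, with 15 of 47 fallen, and tyrosine metabolism, with 17 of 44 fallen, were the other 2 of 127 pathways past camera, and their p were 0.57 and 0.66, adjusted, with an estimated correlation.

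Muscle genes fell for 21 of 30 members and rose for 2 (adjusted p = 1.5e-06, and adjusted p = 0.23 with an estimated correlation), and their share of all counts was 0.377 ± 0.0088% against 0.542 ± 0.0115% in the controls. Genes of neurons and synapses rose for 15 of 44 and fell for 1 (adjusted p = 0.00086, and adjusted p = 0.064 with an estimated correlation). Odorant receptors rose for 25 of 143 and fell for 4 (18 and 4 when adjusted over the list alone), with adjusted p = 0.028, and adjusted p = 0.75 with an estimated correlation. An odorant receptor without a number (GB45078) rose by 0.94 ± 0.10. Immune genes rose for 9 of 18 and fell for 3 (adjusted p = 0.028, and adjusted p = 0.34 with an estimated correlation). Ribosomal proteins rose for 16 of 79 and fell for 0 (adjusted p = 0.028, and adjusted p = 0.76 with an estimated correlation). Among 7 clock genes, 2 rose, 2 fell and 3 did not pass, and period (GB52077) fell by 0.68 ± 0.07. Tyrosine 3-monooxygenase (GB40967), the first enzyme of dopamine synthesis, rose from 136 ± 9.2 to 194 ± 3.0 CPM, among 23 biogenic amine genes of which 9 rose and 2 fell. Of 13 foraging genes, 5 rose and 3 fell, and of 15 neuropeptide genes 4 rose and 1 fell, with the corazonin receptor (GB44824) up by 0.53 ± 0.07. Gustatory receptor 10 (GB44013), ionotropic receptor 25a and glucose dehydrogenase (GB43005) fell by 2.66 ± 0.47, 0.22 ± 0.06 and 1.34 ± 0.07.

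With edgeR, 3825 of 12950 genes passed, 1935 higher and 1890 lower, and 350 of them changed at least 2-fold. Nothing in the labels separates pollen collection from task, age or colony, so these may differ too. Ionotropic receptor 25a had about the same fold, -0.20 to -0.23, but no longer passed without any of the 3 pear libraries, with all 18 libraries in the fit or with only the 6 compared.

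**Figure D2:**
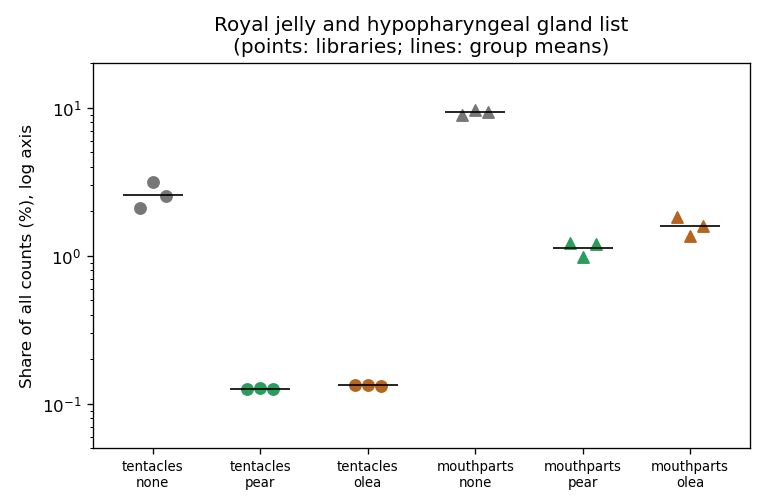
The share of all counts taken by the royal jelly and hypopharyngeal gland list is shown per library (points) with group means (lines), in percent on a log axis. Control libraries averaged 2.59% in the tentacles and 9.34% in the mouthparts, above each pollen group of the same tissue.

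Tentacles of bees with olea pollen differed from control tentacles in much the same genes. The royal jelly family gene GB55204 again fell to near 0, at 0.439 ± 0.085 CPM against 3668 ± 632 CPM, and the list took 0.133 ± 0.00096% of counts. The nuclear receptors HR38 (GB49295) and NR4A2 (GB40074), which belong to the same receptor class, rose by 1.52 ± 0.10 and 1.55 ± 0.07 in log2, to 23.3 ± 0.96 and 137 ± 2.0 CPM. Apidaecin (GB47546) rose by 1.87 ± 0.20, while defensin-1 (GB41428), another antimicrobial peptide, fell from 130 ± 21 to 50.8 ± 4.3 CPM. Hsc3 (GB49117) fell by 1.09 ± 0.05.

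Genes of neurons and synapses rose for 21 of 44 members and fell for 0 (22 and 0 when adjusted over the list alone), and this call held with an estimated correlation (adjusted p = 0.024). The vesicular amine transporter (GB42802), which loads amines into synaptic vesicles, rose from 56.7 ± 2.1 to 82.8 ± 0.27 CPM. Heat shock proteins fell for 17 of 26 and rose for 0, and the royal jelly list fell for 18 of 26 and rose for 3, and both calls held with an estimated correlation (adjusted p = 0.024). Ribosomal proteins rose for 13 of 79 and fell for 1 (adjusted p = 0.0051, and adjusted p = 0.64 with an estimated correlation). Of 30 muscle genes, 3 rose, 7 fell and 20 did not pass, and their share of counts was 0.528 ± 0.0044%. Odorant receptors rose for 20 of 143 and fell for 4, without passing as a list (adjusted p = 0.093). Odorant binding proteins rose for 6 of 18 and fell for 2, among them GB46226, down by 0.68 ± 0.05. Of 30 fatty acid and hydrocarbon genes, 7 rose and 4 fell, with an elongase (GB54404) down by 1.99 ± 0.09. Gustatory receptor 10 (GB44013) had no count with olea pollen, which made it at least 22.2-fold lower than in the controls (0.804 ± 0.25 CPM). Protein processing in the endoplasmic reticulum fell for 54 of 143 genes and rose for 8 (adjusted p = 1.9e-06, and adjusted p = 0.29 with an estimated correlation). Aminoacyl-tRNA biosynthesis, N-glycan biosynthesis, tyrosine and butanoate metabolism also were past camera toward lower levels, and none of the 127 pathways was with an estimated correlation.

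Of 12950 genes, 3617 passed, 1864 higher and 1753 lower. Pear and olea calls shared 1386 genes that rose and 1283 that fell, against 279 and 256 by chance, and 11 genes went opposite ways. Both comparisons use the same 3 control libraries, which can add to the overlap. At an unadjusted p under 0.01, 1258 genes that rose and 1131 that fell were shared, against 236 and 207 by chance. In 20 simulations of unchanged groups with shared controls the averages were 9.30 and 9.25. With no gene changed, these simulations cannot show how much the shared controls add where many genes change.

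Olea and pear pollen were compared directly in the tentacles, where few genes passed in the fit that includes the control libraries. Muscle genes were higher with olea pollen for 18 of 30 members, lower for 1, and not passed for 11 (20 and 1 when adjusted over the list alone). The muscle list had a median log2 difference of 0.48 (camera adjusted p = 3.6e-18, and adjusted p = 0.092 with an estimated correlation). The axonemal dynein heavy chain gene GB55144, of a motor protein of cilia, fell from 41.4 ± 0.84 CPM with pear to 21.3 ± 1.7 CPM with olea. The detoxification gene cytochrome P450 6a14 (GB51383) rose by 1.22 ± 0.14 and transglutaminases GB45708 and GB45714 by 1.01 ± 0.09 and 0.84 ± 0.10. Tyrosine 3-monooxygenase (GB40967) was at 132 ± 5.1 CPM with olea and 194 ± 3.0 CPM with pear, a difference of -0.55 ± 0.05.

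The lists of odorant binding proteins, with 2 of 18 higher, and immune genes, with 2 of 18 lower, moved little. An apidaecin gene (GB46236) fell by 0.98 ± 0.16 with olea. Cytoplasmic actin (GB43029) was higher at 23.1 ± 6.5 against 9.66 ± 0.33 CPM, and missed the threshold with all 18 libraries in the fit. Of 18 members with the smallest p of their list, 8 did not pass, among them the cGMP-dependent protein kinase (GB49907), at -0.36 ± 0.09 and adjusted p = 0.064. GB49907 passed with DESeq2 (-0.36), limma-trend on log2(FPKM + 1) (-0.35), only the 6 libraries (-0.36) and thinned counts (-0.38), and under no other alternative. By camera 0 of 127 pathways passed, with 24 at an unadjusted p under 0.05, and 0 passed with an estimated correlation.

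In all, 337 of 12950 genes passed by edgeR, 247 higher and 90 lower with olea, and 1743 had an unadjusted p under 0.05. Of the calls 73.3% were higher here, 54.3% with only the 6 libraries in the fit and 63.2% with DESeq2. The count fell to 143 to 186 without any of the 6 libraries, as 167, 143 and 186 without pear replicates 1, 2 and 3 and 153, 178 and 162 without olea replicates 1, 2 and 3, and it was 533 with DESeq2 and 1413 with only the 6 libraries in the fit.

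**Figure D3:**
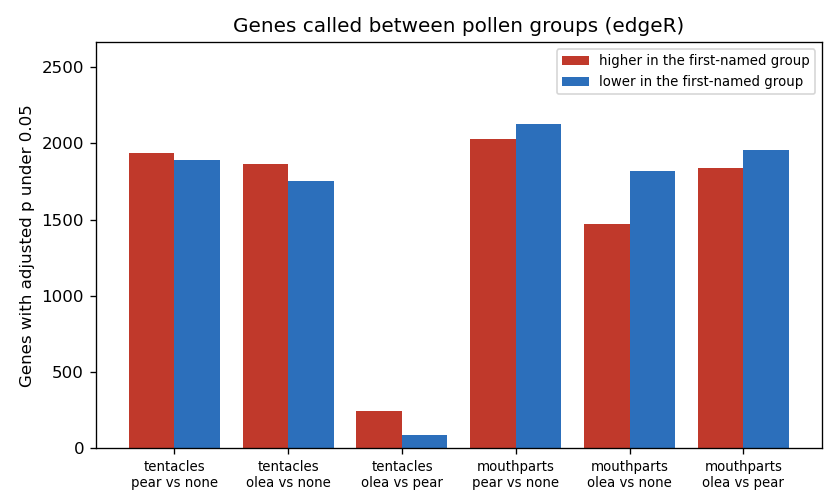
Bars give the number of genes with adjusted p under 0.05 (y axis) in each comparison of pollen groups (x axis), red for higher and blue for lower in the first-named group. In fits that include the control libraries, the tentacles differed in 337 genes between olea and pear and the mouthparts in 3793.

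Mouthparts of bees with pear pollen were compared with control mouthparts. Several royal jelly family genes fell, with GB55205, the most abundant transcript of the control mouthparts, going from 44299 ± 2010 CPM to 3.93 ± 1.4 CPM (n = 3 each). Phenoloxidase 2 (GB44996), an enzyme of melanin formation, fell from 170 ± 25 to 7.98 ± 0.64 CPM, and cytochrome P450 6a14-like (GB49876) from 113 ± 4.4 to 7.43 ± 0.096 CPM. Fatty acid synthase (GB53412) fell from 1363 ± 8.0 to 447 ± 20 CPM and Hsp90 (GB40976) from 4005 ± 139 to 1644 ± 64 CPM. Gudu (GB49219) rose by 4.57 ± 0.15 in log2, from 1.12 ± 0.32 to 26.6 ± 0.13 CPM. Tyrosine 3-monooxygenase (GB40967) rose from 872 ± 29 to 2021 ± 51 CPM, and alpha-methyldopa hypersensitive protein (GB45938) rose by 1.83 ± 0.17.

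Of the royal jelly list, 21 of 29 members fell and 2 rose (21 and 3 when adjusted over the list alone), with camera adjusted p = 8.8e-12, and adjusted p = 0.51 with an estimated correlation. Its share of counts was 1.14 ± 0.129% against 9.34 ± 0.328% in the controls. Fat body genes, which include storage proteins, fell for 11 of 17 and rose for 1 (adjusted p = 1.9e-05, and adjusted p = 0.51 with an estimated correlation). Heat shock proteins fell for 13 of 26 and rose for 0 (adjusted p = 7.2e-07, and adjusted p = 0.082 with an estimated correlation). Detoxification enzymes fell for 38 of 99 and rose for 11 (adjusted p = 0.00016, and adjusted p = 0.51 with an estimated correlation). Digestive proteases and lipases fell for 37 of 93 and rose for 16 (adjusted p = 0.021, adjusted p = 0.51 with an estimated correlation, and adjusted p = 0.057 without the mouthparts replicates 2 described below), with the serine protease GB41408 down from 10.3 ± 1.5 to 0.610 ± 0.23 CPM. Oxidative phosphorylation genes fell for 33 of 65 and rose for 1 (adjusted p = 2.5e-07, and adjusted p = 0.51 with an estimated correlation). Ribosomal proteins fell for 20 of 79 and rose for 1 (adjusted p = 9.9e-05, and adjusted p = 0.75 with an estimated correlation).

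Genes of neurons and synapses rose for 13 of 42 and fell for 1 (adjusted p = 0.015, and adjusted p = 0.51 with an estimated correlation). Among carbohydrate genes 11 of 58 rose and 17 fell, with an aldolase (GB40734) down by 1.99 ± 0.08. Of 29 fatty acid genes 10 rose and 11 fell. Of 6 chemosensory proteins 2 rose and 2 fell, with GB55547 down by 0.68 ± 0.08. Among 11 eye photoreceptor genes 1 rose and 5 fell, and of 12 neuropeptide genes 4 rose and 1 fell, with the corazonin receptor (GB44824) up from 52.0 ± 0.92 to 106 ± 3.4 CPM. The clock gene cryptochrome 2 (GB51095) rose by 0.71 ± 0.08, and an odorant binding protein (GB53371) fell by 1.54 ± 0.11. Odorant receptor 82a (GB50053) had 3 counts in the pear libraries together, and its ratio of control to pear was 42.4 (95% interval 14.0 to 210). Of 31 muscle genes 6 rose and 5 fell, with muscle-specific protein 20 (GB40253) up from 130 ± 14 to 394 ± 37 CPM. Replicate 2 stood apart in both pollen groups, with muscle at 4.03% of counts against 2.97 and 2.89% in the other pear libraries and 3.12 and 3.16% in the other olea libraries. Without both replicates 2, 8 muscle genes rose and 12 fell with pear, and the list median went from 0.10 to -0.09. Of 126 pathways, 20 fell by camera, among them tyrosine metabolism, oxidative phosphorylation and carbon metabolism, and 0 did with an estimated correlation.

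With edgeR, 4157 of 12285 genes passed, 2028 higher and 2129 lower. On log2(FPKM + 1), which moved the median of all genes by 0.12, 73.5% of calls were higher against 48.8% here. With the trend on transcript length taken out, 2 lists no longer passed camera, which compares a list with the other genes. The median of ribosomal proteins went from -0.13 (quartiles -0.20 and -0.07) to -0.05 (-0.11 and 0.00, adjusted p = 0.84). That of neurons stayed close, from 0.21 (-0.04 and 0.41) to 0.19 (-0.07 and 0.44, adjusted p = 0.11), while the mean z of the other genes went from -0.0158 to 0.175. Fatty acid synthase, GB41408, GB53371, the corazonin receptor, GB55547, GB45938 and odorant receptor 82a lost their calls when both collecting groups were read as pear, and 1809 genes passed then.

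**Figure D4:**
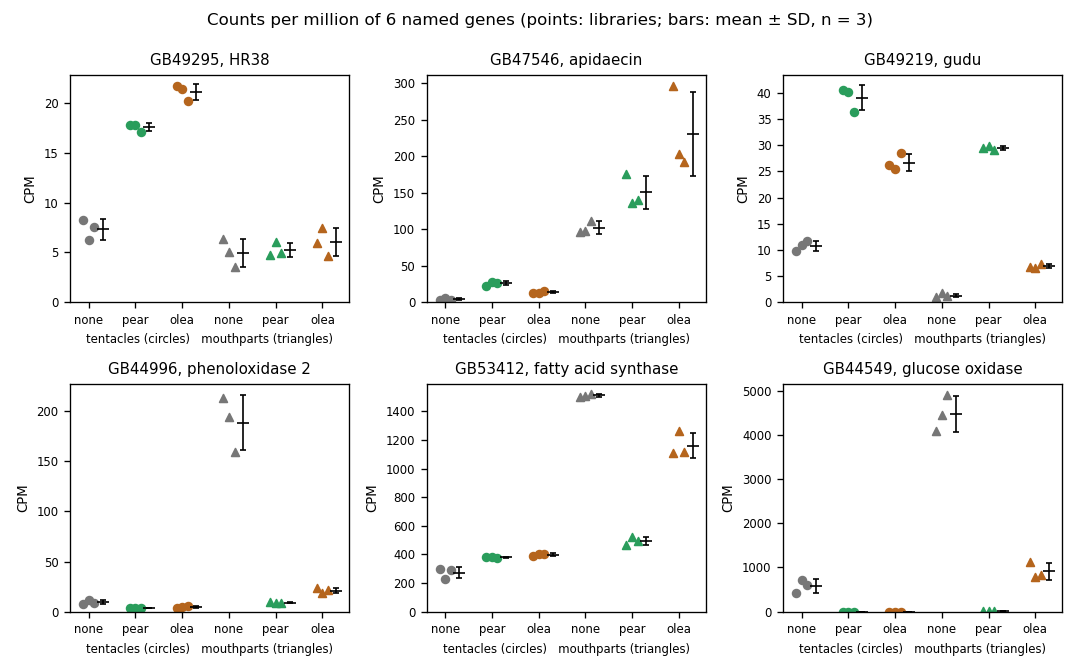
Panels show CPM (y axis, from 0) of 6 named genes in each library (points), by pollen group (x axis) and tissue (circles for tentacles, triangles for mouthparts), with mean ± SD (bars, n = 3). Levels are scaled over all 18 libraries, and glucose oxidase is near 0 in the mouthparts with pear pollen but not in those with olea pollen.

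Mouthparts of the olea group were also compared with control mouthparts. Royal jelly family genes fell here too, among them GB55204 from 8362 ± 321 CPM to 14.9 ± 14 CPM and GB45796 from 585 ± 42 to 1.14 ± 0.40 CPM. Replicate 1 of olea was the highest, with GB55204 at 31.5 CPM against 5.39 and 7.67 CPM, and both genes also passed as lower without it. Phenoloxidase 2 (GB44996) fell by 3.15 ± 0.12 in log2, cytochrome P450 6a14-like (GB49876) by 1.58 ± 0.07 and Hsp90 (GB40976) by 1.10 ± 0.06. A bee antimicrobial peptide (GB47318) rose from 9.52 ± 1.2 to 39.8 ± 11 CPM and a peritrophin-domain gene (GB52294), of a family that binds chitin, from 11.7 ± 0.46 to 43.8 ± 4.5 CPM. Malvolio (GB54097), a metal ion transporter gene known from work on foraging, rose from 225 ± 3.9 to 337 ± 22 CPM.

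The royal jelly list fell for 20 of 29 members and rose for 2 (22 and 3 when adjusted over the list alone), with adjusted p = 3.4e-10, and adjusted p = 0.68 with an estimated correlation, and took 1.59 ± 0.225% of counts. Heat shock proteins fell for 16 of 26 and rose for 1 (adjusted p = 2.2e-06, and adjusted p = 0.093 with an estimated correlation). Fat body genes fell for 8 of 17 and rose for 1 (adjusted p = 0.0028, and adjusted p = 0.84 with an estimated correlation). Detoxification enzymes fell for 28 of 99 and rose for 1 (adjusted p = 0.0036, and adjusted p = 0.84 with an estimated correlation). Without both replicates 2, which had most muscle, fat body (adjusted p = 0.11), detoxification (0.095) and odorant receptors (0.064) no longer passed. Oxidative phosphorylation genes rose for 17 of 65 and fell for 2, and ribosomal proteins rose for 14 of 79 and fell for 0 (both adjusted p = 0.0013, and adjusted p = 0.84 with an estimated correlation). Odorant receptors, near the floor in this tissue, fell for 10 of 54 (adjusted p = 0.0496, and adjusted p = 0.76 with an estimated correlation), with odorant receptor 13a-like (GB52371) at 0.278 ± 0.12 against 1.41 ± 0.54 CPM. The odorant binding protein GB55593, abundant in the tentacles, fell in the same libraries from 174 ± 29 to 16.2 ± 10 CPM. The chemosensory protein GB54970, whose best KEGG hit carries an unrelated name, rose by 1.19 ± 0.08. Of 8 gustatory receptors 1 fell and 7 did not pass, and of 4 ionotropic receptors 1 fell, ionotropic receptor 93a (GB50521), by 1.31 ± 0.29. Of 12 foraging genes 2 rose and 3 fell, and of 46 cuticle genes 4 rose and 10 fell. Ribosome, oxidative phosphorylation and Toll and Imd signalling were the 3 of 126 pathways past camera, all higher, with adjusted p = 0.96, 0.96 and 0.83 with an estimated correlation.

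In all, 3293 of 12285 genes passed, 1472 higher and 1821 lower. Pear and olea calls shared 796 genes that rose and 857 that fell, against 243 and 316 by chance, while 180 genes went opposite ways. Both use the same controls. At an unadjusted p under 0.01 they shared 705 and 785 genes, against 193 and 262 by chance. Averages were 9.95 and 9.70 in 20 simulations of unchanged groups, which cannot show how much shared controls add where many genes change. With the length trend taken out 4 lists no longer passed. Ribosomal proteins went from a median of 0.09 (quartiles 0.02 and 0.18) to 0.05 (-0.01 and 0.12, adjusted p = 0.61) and oxidative phosphorylation from 0.14 (-0.01 and 0.32) to 0.10 (0.00 and 0.26, adjusted p = 0.087). The others stayed close, odorant receptors from -0.34 (-0.85 and 0.09) to -0.35 (-0.87 and 0.10, adjusted p = 0.077) and detoxification from -0.10 (-0.52 and 0.06) to -0.09 (-0.52 and 0.07, adjusted p = 0.060). Their mean z differed from that of the other genes by -0.823 (before -0.830) and -0.741 (before -0.947).

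Olea and pear differed widely in the mouthparts. Enzymes that the hypopharyngeal gland secretes were higher with olea, alpha-amylase (GB49854), which splits starch, at 176 ± 68 against 0.193 ± 0.17 CPM and glucose oxidase (GB44549) at 829 ± 170 against 7.67 ± 0.44 CPM. Control mouthparts had 557 ± 212 CPM of alpha-amylase (GB49854) and 4031 ± 359 CPM of glucose oxidase (GB44549). Cytochrome P450 4C1 (GB47270) was higher by 4.56 ± 0.14 in log2 and fatty acid synthase (GB53412) by 1.24 ± 0.07. Gudu (GB49219) fell by 2.09 ± 0.12, alpha-methyldopa hypersensitive protein (GB45938) by 1.80 ± 0.17 and the corazonin receptor (GB44824) by 0.94 ± 0.08.

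Oxidative phosphorylation genes were higher with olea for 52 of 65 members and lower for 1 (57 and 1 when adjusted over the list alone), with a median of 0.39 (camera adjusted p = 2.3e-15, and adjusted p = 0.54 with an estimated correlation). Ribosomal proteins were higher for 54 of 79 and lower for 0 (69 and 0 when adjusted over the list alone), with adjusted p = 2.2e-13, and adjusted p = 0.54 with an estimated correlation. Log ratios in this comparison fell with transcript length (Spearman -0.359 across 8446 genes, which are not independent replicates). With that trend taken out, 50 of 64 oxidative phosphorylation genes and 16 of 79 ribosomal proteins were higher, and the ribosomal list no longer passed camera (adjusted p = 0.82), with a median of 0.12 (quartiles 0.05 and 0.17) in place of 0.24 (0.19 and 0.30). Muscle genes were higher for 5 of 31 and lower for 1, and for 15 and 6 without both replicates 2, where the list passed (median 0.20, adjusted p = 0.035, and adjusted p = 0.55 with an estimated correlation). The royal jelly list was higher for 12 of 29 and lower for 3 (adjusted p = 0.00099, and adjusted p = 0.54 with an estimated correlation). GB55205 was at 418 ± 360 CPM with olea, with 833 CPM in replicate 1 against 182 and 241 CPM in replicates 2 and 3. Immune genes were higher for 9 of 18 and lower for 1 (adjusted p = 0.025, and adjusted p = 0.54 with an estimated correlation), with peptidoglycan-recognition protein S2 (GB47805), which binds bacterial wall material, up by 1.02 ± 0.10. Fat body genes were higher for 6 of 17 and lower for 0 (adjusted p = 0.019, and adjusted p = 0.54 with an estimated correlation). Genes of neurons and synapses were lower for 12 of 42 and higher for 2 (adjusted p = 0.040, adjusted p = 0.54 with an estimated correlation, and adjusted p = 0.11 without both replicates 2). Of 19 biogenic amine genes 1 was higher and 6 lower, and of 7 clock genes 3 were lower, with period (GB52078) at -0.70 ± 0.10. Odorant receptor 82a (GB50053), near the floor with pear, had a ratio of olea to pear of 22.5 (95% interval 7.21 to 113). By camera, 15 of 126 pathways were higher, led by ribosome, with 89 of 127 genes higher, and oxidative phosphorylation, with 71 of 102 (both adjusted p = 0.74 with an estimated correlation).

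In all, 3793 of 12285 genes passed, 1835 higher and 1958 lower with olea. On log2(FPKM + 1), 26.7% of the calls were higher against 48.4% here, and the list of neurons no longer passed with the length trend taken out (adjusted p = 0.28). Its median went from -0.24 (quartiles -0.37 and 0.04) to -0.15 (-0.41 and 0.03), and its mean z differed from that of the other genes by -0.623 in place of -0.981.

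Whether a pollen effect differed between the tissues was tested as an interaction. HR38 (GB49295) rose in the tentacles with pear and did not pass in the mouthparts (0.08, adjusted p = 0.80), and the interaction was -1.19 ± 0.25 (adjusted p = 0.0031). Fatty acid synthase (GB53412) fell in the mouthparts with pear and rose by 0.46 ± 0.08 in the tentacles, with an interaction of -2.09 ± 0.11. Phenoloxidase 2 (GB44996) fell more in the mouthparts, at -3.03 ± 0.23 for pear and -2.22 ± 0.22 for olea. Tyrosine 3-monooxygenase (GB40967) had interactions of 0.69 ± 0.08 for pear, where it rose in both tissues, and 0.78 ± 0.08 for olea, where it rose in the mouthparts and did not pass in the tentacles (-0.04, adjusted p = 0.60).

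By edgeR, 1706 of 13361 genes had an interaction for pear, 729 higher and 977 lower in the mouthparts than in the tentacles, and 2056 for olea, 659 and 1397. On log2(FPKM + 1), where the median moved by 0.14 for pear, 1926 of 2569 calls were higher for pear against 42.7% here and 50.5% for olea against 32.1%, and with DESeq2 43.3% were for olea. Genes called between olea and pear in both tissues were no more often alike than opposite, with 63 of 126 going the same way.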

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

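The tests of a shared mixture of gland cells, of control bees of another task or age, and of tentacles RNA in the control mouthparts (the count limits last) were chosen only after the result was seen, as were the fits with the length trend taken out, with thinned counts and without replicate 2 of the mouthparts pear and olea groups.

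The effect of pear pollen differed between the tissues, by the interaction term in edgeR, for 24 of the 45 named genes tested, and that of olea pollen for 27 of 46. The values here are interactions in log2, the effect in the mouthparts minus that in the tentacles. For pear 10 of the genes had a higher value in the mouthparts and 14 a lower value, and for olea 17 and 10. The named genes were chosen in the same libraries by a large change or the smallest p of a list. A share above that of all genes can follow from this choice. In all 1706 of 13361 genes (12.8%) passed for pear and 2056 (15.4%) for olea.

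With pear pollen the higher values were 2.70 for gudu (GB49219), 2.34 for chitinase-3-like protein 1 (GB42434) and 1.68 for alpha-methyldopa hypersensitive protein (GB45938). Glucose dehydrogenase (GB43005) had 1.63, period (GB52077) 0.85 and the elongase GB54404 0.72. Tyrosine 3-monooxygenase (GB40967) had 0.69, the odorant binding protein GB46226 0.60, the corazonin receptor (GB44824) 0.49 and Hsc3 (GB49117) 0.27. Lower values were -0.35 for ribosomal protein SA (GB43548), -0.54 for Hsp90 (GB40976), -0.78 for the leucine rich repeat gene GB50423, -0.99 for the chemosensory protein GB52326 and -0.999 for the carboxylesterase GB53755. They were -1.19 for HR38 (GB49295), -1.44 for TRPV5 (GB44065), -2.09 for fatty acid synthase (GB53412) and -2.25 for apidaecin (GB47546). They were -3.03 for phenoloxidase 2 (GB44996), -3.31 for cytochrome P450 6a14-like (GB49876), -3.40 for the odorant receptor GB45078 and -3.90 for the serine protease GB41408. The value of GB45078, not tested in the fit of the mouthparts, rests on 4 counts in the mouthparts with pear. Odorant receptor 82a (GB50053) had -5.13, a fitted value that rests on 3 counts in the mouthparts with pear.

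With olea pollen 5 royal jelly family genes fell less in the mouthparts, with 6.19 for GB55205, 6.09 for GB45797, 3.86 for GB55204, 3.58 for GB55212 and 3.10 for GB45796. Without mouthparts olea replicate 1, the highest of its group, these were 5.21, 4.82, 2.68, 2.31 and 2.85, and all passed. Gustatory receptor 10 (GB44013) had 5.12, a fitted value that rests on 0 counts in the tentacles with olea and is no bound. The trypsin inhibitor-like gene GB50121 had 1.35, chitinase-3-like protein 1 (GB42434) 1.27, GB42427 0.95 and aldolase (GB40734) 0.95. Tyrosine 3-monooxygenase (GB40967) had 0.78, the chemosensory protein GB54970 0.78, the CCHamide-2 receptor (GB40054) 0.51 and the elongase GB54404 0.50. The odorant binding protein GB46226 had 0.46, Malvolio (GB54097) 0.43 and Hsc3 (GB49117) 0.36. Lower values were -0.33 for Hsp90 (GB40976), -0.45 for the carboxylesterase GB53755, -0.93 for the chemosensory protein GB52326 and -0.94 for NR4A2 (GB40074). They were -1.10 for cytochrome P450 6a14-like (GB49876), -1.22 for the vesicular amine transporter (GB42802), -1.25 for HR38 (GB49295) and -1.26 for ionotropic receptor 93a (GB50521). Phenoloxidase 2 (GB44996) had -2.22 and odorant receptor 13a-like (GB52371) -2.26.

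Of the lists, 8 differed between the tissues with pear by camera, and each lost its call with an estimated correlation. Median interactions were -0.31 for ribosomal proteins (adjusted p = 0.41 with an estimated correlation), -0.16 for detoxification enzymes (0.29), -0.43 for eye photoreceptors (0.29) and -0.51 for fat body genes (0.24). They were -0.46 for immune genes (0.24), 0.55 for muscle (0.46, and a median of 0.37 without replicate 2 of the mouthparts pear and olea groups), -0.31 for odorant receptors (0.24) and -0.28 for oxidative phosphorylation (0.34). With olea 3 lists differed, neurons and synapses at -0.31 (0.84), odorant receptors at -0.53 (0.48) and royal jelly at 0.23 (0.84). The list of neurons and synapses no longer passed camera without replicate 2 of the mouthparts pear and olea groups (adjusted p = 0.11). Without members of at most 3 counts in a group, the median of odorant receptors was -0.25 for pear and -0.33 for olea.

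Gland transcripts were abundant in the control tentacles and near absent with pollen, and the royal jelly list, with 31 members of which 14 reached 1 CPM in tentacles with pollen and 1 is held by another list, took 2.59% of counts with GB55205 highest at 11356 ± 3161 CPM. Genes restricted to the mouthparts argue against whole mouthparts RNA carried over into the control tentacles, as their median excess there was 0.984% of their control mouthparts level, against 22.2% for 14 abundant gland genes. A shared mixture of gland cells stays open, as 2 of the 14 genes, GB43247 and GB55207, lay more than 5-fold below the median share in each of the 3 libraries, short of the 3 set as limit. Alpha-amylase (GB49854), not on the list and examined after its values were seen, would be another. These 3 kept 55.2, 16.5 and 31.2% of their control level in the mouthparts with olea, against 0.175% for GB55204, the lowest, so another source there is not excluded. The glucose oxidase genes GB44549 and GB51446 kept 20.3 and 33.3% too, but with shares of 13.0 and 3.82% they were not below that limit in each library. Control bees of another task or age stay open, as the fat body list fell in 2 of the 4 comparisons with the controls (1 without the mouthparts replicates 2) and no label gives task or age, and both explanations cannot be told apart from an effect of pollen collection, the untested biological one.

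More genes differed between olea and pear in the mouthparts (3793) than in the tentacles (337). The gap was smaller with only the 6 libraries in the fit (3286 and 1413). It was also smaller at an adjusted p under 0.05 from the deposited p-values (3074 and 1488). The fits of only the 6 libraries leave the controls out, so the size of the gap depends in part on the control libraries. A trend with transcript length is argued against as the whole cause, since 3706 genes passed with it taken out, and so is the depth of the pear libraries, since 3694 passed at 1 total per library. If the libraries with conflicting labels came from pear pollen, genes called in both tissues would go the same way about as often as not. Of these, 50% did (63 of 126, exact 95% interval 41 to 59, which takes the genes as independent). Unrelated responses of the tissues to olea and pear would give the same share, so it cannot decide the question. The deposited comparisons set the LH against the YH libraries, and across tissues LC against LH and YC against YH. The reading as pear pollen stays open, and so does a biological difference between the tissues, which was not tested further.

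Some genes typical of the tentacles, odorant receptors among them, were higher in the control mouthparts than in the mouthparts with pollen. By camera the receptor list was lower with olea (adjusted p = 0.0496) and did not pass with pear (adjusted p = 0.28). The odorant binding protein list took 0.678% of counts in control mouthparts, 1.03% with pear and 0.752% with olea. The genes examined here were chosen for a low level in the mouthparts with pollen relative to the tentacles. That level was then subtracted, which favours a positive excess. A small amount of tentacles RNA in the control mouthparts would give all of these genes the same excess share of their control tentacles level. The medians were close, at 0.691% for 30 odorant receptors, 0.897% for 4 odorant binding proteins and 0.638% for 2 other genes. Against 1 share, 16 of the 30 receptors had control counts outside counting error (unadjusted p under 0.05) around a pooled share of 0.863%, where 1.5 were due by chance, and their quartiles of 0.255 and 1.24% lay 4.87-fold apart. That distance depended on a limit on the counts due, 3.24-fold at 20 (11 receptors) and 1.27-fold at 40 (4 receptors). A wider set of 58 receptors, tested first and with no limit on the level in the mouthparts with pollen, had a median of 0.666%. Its quartiles were -0.0225 and 1.55%. For the 30 receptors a lower quartile of 0 or less was set as counting against 1 share. So tentacles RNA cannot be told apart from an effect of pollen collection, which was not tested.

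Libraries were also divided into groups of the same sizes in other ways. For each pollen comparison the 10 splits were too few for a share under 0.05, and 1 split, the real one, gave as many genes. The highest of the others gave 2 genes against 3825 (tentacles, pear and none), 0 against 3617 (tentacles, olea and none) and 5 against 337 (tentacles, olea and pear). In the mouthparts it gave 1 against 4157 (pear and none), 3 against 3293 (olea and none) and 1 against 3793 (olea and pear). Each of these other splits mixes the groups compared, which adds any pollen effect to the spread between libraries. So these counts do not judge chance. For the tissues 1 of 100 splits gave as many as 11027, and the highest other gave 7678. The other splits mix or swap the tissues in at least 1 pollen group, and mixing adds the tissue difference to the spread between libraries. So this count does not judge chance. For the interaction with pear 7 of 100 splits gave as many as 1706, and the highest other gave 5479, several times the real count. The 6 others all kept the pollen groups of at least 1 tissue intact and so carry its pollen effect. The draw also allowed a swap of the pollen labels of 1 tissue, which adds the effects of both tissues together. So the count for pear does not judge chance. For the interaction with olea 2 of 100 gave as many as 2056, and the highest other, which also kept at least 1 tissue intact, gave 4590. So this count does not judge chance either. Splits that mixed the groups of both tissues gave at most 1 gene for pear and 5 for olea, but they add the pollen effect to the spread between libraries.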

How the results depend on the processing

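The fits with the length trend taken out, thinned counts, the royal jelly list removed, LH and YH together as pear, the tissue difference without some groups, the replicate block within each pollen group, the fits without both mouthparts libraries with most muscle, and the estimated correlation for pathways were tests chosen only after the result was seen.

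Of the values of named genes under the alternatives, 3592 kept their side of the threshold, 105 kept direction and no longer passed, and 11 newly passed. Among values that passed in the main fit or the alternative, 0 changed sign. Sign changes of values that passed in neither were not counted apart from the 3592. With a log2 fold change of at least 1, 350, 283 and 29 genes passed in the tentacles (pear and none, olea and none, olea and pear), 651, 376 and 477 in the mouthparts, 4457 between tissues, and 445 and 395 for the interactions with pear and olea, as that setting asks for larger changes. For olea and pear in the tentacles, with 337 genes, DESeq2 gave 533, all 18 libraries in the fit 168, only the 6 libraries 1413, and the replicate block 247, and the cause was not tested. The interaction with pear gave 2569 genes with limma-trend on log2(FPKM + 1), and the cause was not tested. With LH and YH together as pear, 1809 genes differed between pear and none in the mouthparts, in place of 4157, and the cause was not tested. With YH alone counted as pear the fit is that of olea and none, with its 3293 genes. Of 33 list calls between pollen groups 5 held with an estimated correlation and fry gave 72, and of 46 pathway calls 0 held, where camera at an unadjusted p under 0.05 gave 22, 21 and 24 in the tentacles and 35, 16 and 30 in the mouthparts.

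Leaving out 1 library gave 2624 to 4162 genes for pear and none, 2422 to 3910 for olea and none and 143 to 186 for olea and pear in the tentacles. In the mouthparts it gave 3081 to 3534, 2303 to 3157 and 2638 to 3877. It gave 10953 to 11142 between tissues and 1259 to 2042 and 1442 to 2178 for the interactions. For olea and pear in the tentacles each of the 6 libraries moved the count by over 1.5 times, to 167, 143 and 186 without pear replicates 1, 2 and 3 and 153, 178 and 162 without olea replicates 1, 2 and 3.

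The tissue difference gave 8648 genes with the controls only, 10734 with the pollen groups only and 10209 without the conflicting libraries. Same-number libraries of both tissues correlated over 0.1 in 2 of 3 pairs of each pollen group. Pairs of different numbers between tissues reached at most 0.0875 (none), 0.0902 (pear) and 0.0779 (olea). So libraries of the same number may be paired between tissues, which the main tests of tissue and interaction left out. Within a tissue 1 of 9 same-number pairs in the tentacles and 3 of 9 in the mouthparts were over 0.1. Other pairs there reached 0.356 and 0.418. The replicate block gave 10989 genes between tissues and 1655 and 1933 for the interactions with pear and olea, and a block within each pollen group 10849, 1312 and 1490. Without the mouthparts pear and olea libraries with most muscle, 4059, 3490 and 3518 genes passed in the mouthparts, 11053 between tissues and 1853 and 2273 for the interactions. Lists that no longer passed then were digestive enzymes with pear, detoxification, fat body and odorant receptors with olea, and neurons between olea and pear and in the interaction with olea. Lists that newly passed were biogenic amines with pear, clock, detoxification and muscle between olea and pear, and venom gland in the interaction with olea, none with an estimated correlation. Shared pear and olea calls numbered 2389 in the tentacles and 1490 in the mouthparts at an unadjusted p under 0.01, against 2669 and 1653. Depth limits receptors near the floor, as 50 of 143 odorant receptors had at most 3 counts in a group of the interaction with pear.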

Other observations

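The test of the tissue name was chosen only after the result was seen.

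The labels call a tissue tentacles, a word not used for a honey bee organ. A candidate explanation is that these are antennae, and 99.3% of 143 tested odorant receptors were higher in them than in the mouthparts. This stays a hypothesis, as it was found and tested on the same data.

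The authors' deposited p-values, unadjusted and under 0.05, covered 4015, 3997 and 2709 genes in the tentacles (pear and none, olea and none, olea and pear) and 4953, 4116 and 4101 in the mouthparts. The fits here gave 5241, 5188 and 1743, and 5401, 4674 and 5059. These counts come from unlike sets of genes. Deposited p-values were given for 11411, 11446 and 11360 genes in the tentacles and 10787, 10687 and 10749 in the mouthparts. The fits here tested 12950 and 12285. Across the genes in both, the log2 fold changes had Pearson correlations of 0.999989 to 0.999998.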
